A study of Triticum aestivum with 18 samples.

How the data were processed

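Gene expression was measured in root apices of bread wheat cultivar Chinese Spring (CS) and of 2 wheat-rye addition lines. An addition line carries the whole wheat genome plus a pair of rye chromosomes, 3R or 6R. Seedlings were moved for 24 h to nutrient solution with 200 µM AlCl3 or to the same solution without it, and roots were sampled at an age of 5 days. Each line and condition had 3 samples, which the labels call biological replicates, for 18 samples in all. Per the labels, the Al and the control sample of a replicate were labelled with Cy3 and Hyper 5 dye and hybridised together on 1 of 9 arrays, and each channel was then deposited as a sample of its own. In each line, 2 arrays had the Al sample in Cy3 and 1 array had it in Hyper 5. Slides were inferred from the prefix of the scanner files that the labels name. Slide 1 held replicates 1 and 2 of 3R and 6R, slide 2 held replicates 1 and 2 of CS, and slide 3 held replicate 3 of all lines. For 6R, the replicate numbers 1 and 2 in the titles are exchanged in the scanner file names. The numbers of the titles were used, and the dye fields go with them.

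The deposited values are log2 intensities for 45220 probe rows, and the submitters' processing notes name limma. The background correction and normalization are not given in the sources used here. Within a line, the sorted values of any 2 samples differ by at most 0.004, whereas those of a 3R and a CS sample differ by up to 0.355, so the deposited values look quantile normalized within each line separately. Sample medians are 7.10 in 3R, 7.22 in 6R and 7.34 in CS, so comparisons of levels between lines rest on separately normalized samples. The lowest log2 value is 5.62, close to a linear intensity of 50 (49.2 in CS), and 37.6% of the rows have a mean under 6.3. Such a floor shrinks the fold changes of dim probes. The table has no detection call, and its control spots are not marked, so all rows were tested. With 3 arrays per line, precision is given as a standard error beside the leading changes of each comparison. Correlations between replicates of a group over all probes were 0.941 to 0.98, and no pair of columns was identical.

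The within-array log2 ratio of Al over control was fitted per probe with limma 3.58.1 in R 4.3.3, with a mean for each line and a shared dye term, which equals a fit to the 18 samples with the array as a fixed block. It leaves 5 residual degrees of freedom, and the prior adds 2.61. Because dyes were balanced 2 to 1, the dye term is needed to keep probe-specific dye effects out of the line means. The pairing comes from the shared arrays: residuals of the 2 samples of an array correlated at 0.722 to 0.855 over probes. Levels of control samples were compared between lines with limma on the single channels, with 6 group means, a dye term and the array as a random block (consensus correlation 0.625). Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 45220 rows, and every adjusted p in the text comes from these fits unless said otherwise. Errors of log2 changes are standard errors (SE) of the moderated fit.

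Genes were named through the platform annotation table, which names 996 rows with 1 symbol each, none with several, and leaves 44224 without a name. Symbols were looked up in a gene table of the assembly GCF_018294505.1, which held 475 of the 553, and used for names alone. A descriptive name was had for 280 rows (121 names), and 716 rows have a LOC number alone (430 numbers), which says nothing about function. In the table of named genes a comparison names, in each direction, the 12 genes of largest change past the threshold whose ratio had that sign in all 3 arrays of the line (9 of 9 for the mean, no overlap of 3 against 3 for levels), with 1 probe per gene, the one of smallest p. For differences of responses the 6 largest are named, and where fewer than 5 pass, the 5 of smallest p are given as not past the threshold. LOC numbers were limited to 2 in each direction. Genes of ALMT and MATE transporters were to be given always, and no named row is one. The list of ALMT and MATE genes is 1 of 25 gene lists fixed by topic, and up to 4 members of smallest p were kept as examples of each. The members of the lists were assigned by hand to symbols, before values were read, because the annotation gives symbols and no descriptions. Probes exist for 16 lists, and the 10 lists with at least 5 probes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. At that setting several probes of a gene count as nearly independent, which can make p too small. The 33 photosynthesis probes come from 7 genes, the 13 sulfur and methionine probes from 2, the 8 chaperone probes from 3 and the 5 proton pump probes from 1. Their correlations estimated from the within-array fit were 0.124, 0.49, 0.158 and 0.839. Lists for photosynthesis, seed storage and histones stand for other cell types or cell states.

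The samples, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were fits without the array block, with a random block, without the dye term, with the slide as a block, and on the arrays compared alone. Further ones were quantile normalization across all samples, median centring, removal of the dimmest probes, a trended robust prior, stricter thresholds, averaging of probes of one gene, and leaving out each array in turn. Chosen after seeing the data were a loess of each array's ratios on intensity, a dye term per line, and ratios scaled to one spread of the dye effect. The fits were tested on simulated data of 45220 probes in which 200 had been changed in 3R. For the simulated 3R response, 31.3% of changes of 0.5, 77.6% of changes of 1 and 95.5% of changes of 2 log2 units were recovered, and 6.2% of calls were unchanged probes. For the simulated difference of 3R minus CS responses the shares recovered were 3%, 59.7% and 89.4%, and for simulated control levels 23.9%, 50.7% and 86.4%. In the data 14.9% of the probes were called for Al in 3R, a far larger share than the 200 changed here. The adjusted p depends on that share, and the simulated noise was independent between probes. The shares recovered therefore do not carry over directly to the Al responses.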

Results

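Transcript levels in root apices of CS and of the addition lines 3R and 6R were compared between plants kept for 24 h in 200 µM AlCl3 and plants kept in control solution. Each of the 6 groups held 3 samples, and the Al and control samples of a replicate shared an array. The design asks which transcripts respond to Al in each line, whether an added rye chromosome pair goes with another response, and whether the lines differ without Al. The arrays carry 45220 probe rows of log2 intensity. A change with Al is the mean log2 ratio of the 3 arrays of a line, with the dye effect removed.

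In CS, named genes such as rab, PR5 and the catalase gene wcat1 rose with Al, and TaGlu1a, Prx113-F and 3 gibberellin 20-oxidase genes fell. The largest rise among named genes was that of rab, an abscisic acid responsive dehydrin, by 3.66 ± 0.11 on the log2 scale (SE, n = 3 arrays, 12.7-fold, adjusted p = 3.2e-06). PR5, a thaumatin-like pathogenesis-related protein, rose 8.21-fold (log2 3.04 ± 0.20, adjusted p = 4.7e-05). The largest fall was that of TaGlu1a, a beta-glucosidase that releases benzoxazinoids from their glucosides, with a log2 change of -4.08 ± 0.15 (17.0-fold, adjusted p = 5.9e-06). The peroxidase gene Prx113-F fell 9.48-fold (log2 -3.24 ± 0.26).

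Further rises in CS were those of Glc1 (3.92-fold), the catalase gene wcat1 (3.28-fold), the late embryogenesis abundant gene LEA1 (2.86-fold), the zinc finger gene WZF1 (2.79-fold) and U2AF65a, a splicing factor subunit (log2 1.38). COMT1, an O-methyltransferase of lignin synthesis, rose 2.30-fold. Smaller rises were found for PIMT (1.79-fold), a repair methyltransferase of damaged proteins, WSZ2b (1.72-fold), WGA1 (1.59-fold) and the S-adenosylmethionine synthetase gene SAMS (1.53-fold). A second beta-glucosidase gene, Taglu1b, fell 6.90-fold. The gibberellin 20-oxidase genes GA20ox1d, GA20ox1b and GA20ox1a fell 4.31-fold, 3.17-fold and 2.95-fold. The Al samples of CS lay near the floor (mean log2 level under 6.3) for GA20ox1b and GA20ox1a, where changes are compressed, so these 2 folds are not exact. The alpha-amylase gene amy1 fell 3.08-fold and waxy, which encodes granule-bound starch synthase, fell 2.39-fold. PsbO, a subunit of the oxygen-evolving complex, fell 2.23-fold, the phosphomannomutase gene PMM 2.13-fold, the avenin-like gene avnla 1.95-fold and the adenylosuccinate synthase gene AdSS 1.92-fold. All of these passed at an adjusted p of 0.026 or lower in limma and had the same sign in 3 of 3 arrays. Among genes with a LOC number alone, LOC542888 rose 14.1-fold and LOC543235 rose 13.3-fold, while LOC100136980 fell 19.0-fold and LOC542836 fell 9.01-fold.

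The list of dehydrins and LEA proteins rose in CS (camera, adjusted p = 0.0027), with 4 of 10 probes up, none down and 6 not passing. Its call was lost with an estimated correlation (adjusted p = 0.09 with an estimated correlation). Beside rab and LEA1, its members EM (0.36 on the log2 scale, adjusted p = 0.019) and Em (0.23, adjusted p = 0.025) passed. The CS control samples of EM lay near the floor, so the size of its change is not exact. Genes often used as references fell together: 14 of 20 probes fell and 6 did not pass (camera, adjusted p = 1.2e-06), or 17 adjusted over the list alone, and with an estimated correlation the adjusted p = 0.09. All called members are beta-tubulins or an elongation factor, among them tubb2 (log2 -0.77), tubb1 (-0.50) and Tubb4 (-0.74, with a fall in 1 of 3 arrays before the dye effect was removed). In the photosynthesis list 3 of 33 probes fell, from PsbO and PsbP, and none rose. The list as a whole leaned the other way, with a median of 0.27, a mean of 0.17 and an upward test that did not pass (camera, adjusted p = 0.57). In the list of seed storage and endosperm 3 of 42 fell, from ATI and avnla. It had a median of 0.02, a mean of -0.06 and a downward test that did not pass (camera, adjusted p = 0.83). No histone probe of 6 passed. Probes of one gene disagreed for the deoxymugineic acid synthase gene TaDMAS1, of which a probe fell with a log2 change of -1.06 (in 2 of 3 arrays before the dye effect was removed) while another stood at 0.40.

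Over all probes, 5232 rose and 5138 fell with Al in CS, 10370 of 45220 in limma at adjusted p under 0.05. The 2 arrays of slide 2 and the array of slide 3 gave mean changes of 0.94 and 1.03 over these probes in their direction, against 0.97 pooled. The same arrays had called these probes and set their direction, so a mean of that sign on each slide is built in, here and wherever means within slides over called probes follow. Without the dye term 3912 probes passed, without the array block 2388, and without CS replicate 3 there were 6803. With the slide as a further block 1268 passed. Slide 2 held CS arrays alone, so in that fit its effect cannot be told from the CS response there. The fall from 10370 to 1268 therefore does not show whether the CS response holds.

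**Figure D1:**
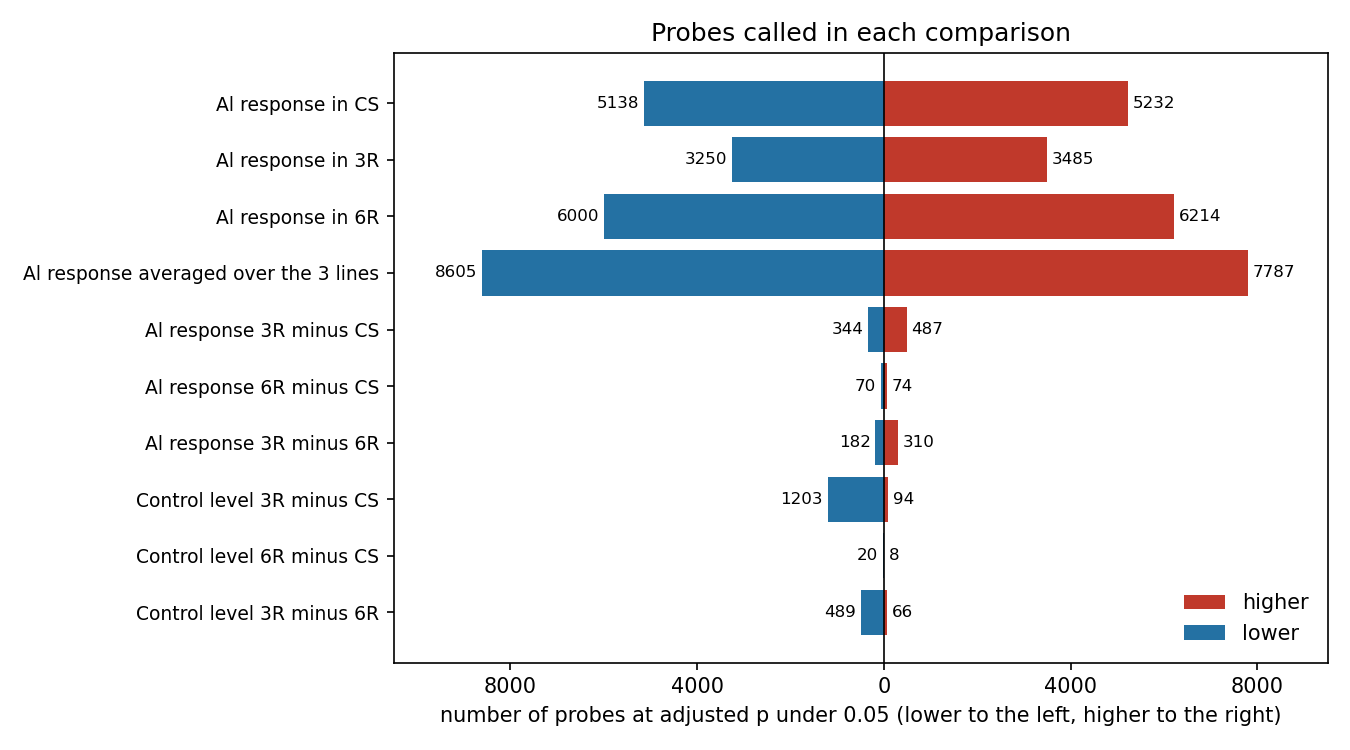
Numbers of probes called in each comparison (horizontal axis, probes at adjusted p under 0.05 in limma), with probes of higher level or larger response to the right and lower to the left. The responses to Al call between 6735 and 12214 probes in single lines, and the differences of responses between lines between 144 and 831.

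In 3R, Al raised PR5 most among the named genes, 17.1-fold (log2 4.09 ± 0.20, SE, n = 3 arrays, adjusted p = 5.7e-05), followed by wcat1 (3.11-fold), Glc1 (2.15-fold), WZF1 (2.07-fold) and cbp2 (2.00-fold). TaGlu1a fell most, 3.96-fold (log2 -1.98 ± 0.15, adjusted p = 0.00026). The dehydrin gene rab did not pass in 3R, at 0.18 ± 0.11 on the log2 scale (adjusted p = 0.35). LEA1 passed at 0.46 (adjusted p = 0.0099), but its ratio was above 0 in 1 of 3 arrays, so that this value rests on the dye term.

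Smaller rises in 3R were those of COMT1 (1.84-fold), WSZ2b (1.72-fold), PIMT (1.67-fold), the ubiquitin conjugation gene UBC1 (1.53-fold), U2AF65a (1.47-fold) and the phytochelatin synthase gene PCS1 (1.30-fold). The gibberellin synthesis genes GA20ox1d, GA20ox1b, GA3ox2-2 and GA20ox1a fell 2.83-fold, 2.21-fold, 2.16-fold and 1.77-fold, where the fold of GA20ox1b is not exact because its Al samples lay near the floor. Prx113-F fell 2.52-fold, waxy 2.24-fold, Taglu1b 2.00-fold, Tubb4 1.87-fold and tubb3 1.85-fold. ATI, an amylase and trypsin inhibitor, fell 1.81-fold and amy1 1.77-fold. LOC543235 rose 13.0-fold and LOC543339 rose 10.6-fold, and LOC100037574 fell 4.02-fold and LOC543138 fell 3.42-fold. Each of these passed at an adjusted p of 0.044 or lower, with 3 of 3 arrays of the same sign.

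The reference genes were the 1 list called in 3R (camera, adjusted p = 0.003), with 5 of 20 probes down and 15 not passing, or 7 down adjusted over the list alone. Its call was lost with an estimated correlation (adjusted p = 0.43 with an estimated correlation). In the metal chelation list 2 of 7 probes rose, from PCS1 and the metallothionein-like gene wali1. Of the 3 probes of wali1, 1 passed at 1.06 on the log2 scale (adjusted p = 0.035), with a ratio above 0 in 1 of 3 arrays before the dye effect was removed, and 2 did not pass. None of the 33 photosynthesis probes and none of the 6 histone probes passed in limma in 3R.

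Over all probes, 3485 rose and 3250 fell with Al in 3R, 6735 in all. Mean changes over these, in the direction called, were 0.86 on slide 1 and 0.91 on slide 3, against 0.88 pooled. Without the dye term 1691 passed, without the array block 735, on the 3R arrays alone 10587, and without 3R replicate 1, 2 or 3 there were 3879, 1905 and 3054.

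In 6R, PR5 rose 14.2-fold (log2 3.83 ± 0.20, SE, n = 3 arrays, adjusted p = 1.8e-05), Glc1 4.14-fold, wcat1 3.47-fold and U2AF65a 2.55-fold. TaGlu1a fell 22.5-fold (log2 -4.49 ± 0.15, adjusted p = 4.7e-06), Prx113-F 10.4-fold, GA20ox1d 7.73-fold and Taglu1b 6.84-fold. LEA1 rose 2.00-fold and rab 1.66-fold (log2 0.73 ± 0.11, adjusted p = 0.0018).

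Smaller rises in 6R were those of COMT1 (2.13-fold), PIMT (1.98-fold), WZF1 (1.96-fold), WSZ2b (1.69-fold), UBC1 (1.57-fold) and SAMS (1.57-fold). The gibberellin synthesis genes GA20ox1b, GA20ox1a and GA3ox2-2 fell 5.00-fold, 3.86-fold and 2.61-fold. The folds of GA20ox1d, GA20ox1b and GA20ox1a, with Al samples of 6R near the floor, and of rab, with control samples near it, are not exact. Falls were also found for amy1 (3.84-fold), PMM (3.17-fold), waxy (2.80-fold), FKBP70, a peptidyl-prolyl isomerase (2.35-fold), and ha1, a plasma membrane proton pump (2.30-fold). All passed at an adjusted p of 0.022 or lower and in 3 of 3 arrays. LOC543235 rose 18.4-fold and LOC778394 rose 15.2-fold, and LOC100136980 fell 18.1-fold and LOC100037574 fell 10.6-fold.

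The list tests called 3 lists in 6R. The reference genes fell, with 14 of 20 probes down and 6 not passing, or 17 down adjusted over the list alone (camera, adjusted p = 1.1e-07, and adjusted p = 0.13 with an estimated correlation). Among heat shock proteins and chaperones 4 of 8 probes fell and 4 did not pass (5 adjusted over the list alone, camera adjusted p = 0.039, and adjusted p = 0.53 with an estimated correlation), with FKBP70, the disulfide isomerase gene PDI (log2 -1.07) and the small heat shock gene hsp16.9A (-0.84). The proton pump list holds 5 probes of ha1 alone, and 3 of them fell, or 4 adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.53 with an estimated correlation). In the metal chelation list 3 of 7 probes rose, 2 fell and 2 did not pass. Its risers were PCS1 and 1 of 3 probes of wali1 (log2 1.13, above 0 in 1 of 3 arrays before the dye effect was removed), and TaDMAS1 fell (-1.37, in 2 of 3 arrays). A single photosynthesis probe of 33, from rbcL, rose (0.91, in 1 of 3 arrays before the dye effect was removed), and a single histone probe of 6, from H2A-2, fell (-0.79).

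Over all probes, 6214 rose and 6000 fell with Al in 6R, 12214 in all. Mean changes over these, in the direction called, were 0.96 on slide 1 and 0.92 on slide 3, against 0.94 pooled. Without the dye term 4430 passed, without the array block 2716, on the 6R arrays alone 7578, and without 6R replicate 1 there were 6419.

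Averaged over the 3 lines, PR5 rose 12.6-fold (log2 3.65 ± 0.12, SE, 9 arrays, adjusted p = 7.9e-07), and wcat1 and Glc1 rose 3.28-fold and 3.26-fold. TaGlu1a fell 11.5-fold (log2 -3.52 ± 0.09, adjusted p = 3.9e-07), Prx113-F 6.29-fold and GA20ox1d 4.55-fold. All had the same sign in 9 of 9 arrays.

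Other genes with the same sign in 9 of 9 arrays were rab (2.88-fold up on average), WZF1 (2.24-fold), U2AF65a (2.14-fold), COMT1 (2.08-fold), PIMT (1.81-fold), WSZ2b (1.71-fold), UBC1 (1.51-fold), EM (1.21-fold) and LTP3, a lipid transfer protein (1.15-fold). Going down were Taglu1b (4.55-fold), GA20ox1b (3.27-fold), GA20ox1a (2.72-fold), waxy (2.47-fold), amy1 (2.42-fold), ATI (1.88-fold), FKBP70 (1.87-fold), AdSS (1.81-fold) and AGP-S, the small subunit of ADP-glucose pyrophosphorylase (1.75-fold). Samples of at least 1 line lay near the floor for rab, EM, LTP3, the GA20ox1 genes, amy1 and ATI, and the floor compresses their mean changes. LOC543235 rose 14.7-fold and LOC778394 rose 9.82-fold, and LOC100136980 fell 9.86-fold and LOC543138 fell 5.90-fold.

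In the mean of the lines 3 lists were called. Reference genes fell in 16 of 20 probes and 4 did not pass (camera, adjusted p = 3.8e-07, and adjusted p = 0.16 with an estimated correlation), and 18 fell adjusted over the list alone. Chaperones fell in 5 of 8 probes, or 6 adjusted over the list alone (adjusted p = 0.037, and adjusted p = 0.43 with an estimated correlation), with FKBP70 (log2 -0.90), PDI (-0.72) and hsp16.9A (-0.39), the last 2 with a fall in 7 of 9 arrays before the dye effect was removed. Dehydrins and LEA proteins rose in 3 of 10 probes (adjusted p = 0.037, and adjusted p = 0.20 with an estimated correlation). In the photosynthesis list 5 probes of the Rubisco large subunit (rbcL and rbcl) rose and 4 of PsbO and PsbP fell, and the list was not called (adjusted p = 0.29). In the metal chelation list 4 of 7 probes rose and 1 fell. The metallothionein-like gene wali1, named after its induction by Al in wheat, passed in 2 of 3 probes, at 1.00 (adjusted p = 0.0017) and 0.73 (adjusted p = 0.013) on the log2 scale, and the ratio of the first was above 0 in 3 of 9 arrays before the dye effect was removed. The lignin list holds 2 probes of COMT1, of which 1 rose by 1.06 and the other stood at 0.23 without passing. The antioxidant list holds 2 probes of wcat1, of which 1 rose by 1.72 and the other stood at 0.09.

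In all, 7787 probes rose and 8605 fell in the mean of the lines, 16392 together, and 9164 without the dye term, of which 9159 were among the 16392 in the same direction. Without the array block 6240 passed, and with the slide as a further block 8156. The mean includes the CS response, which the slide block does not retest, so the count with that block does not retest the mean either.

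**Figure D2:**
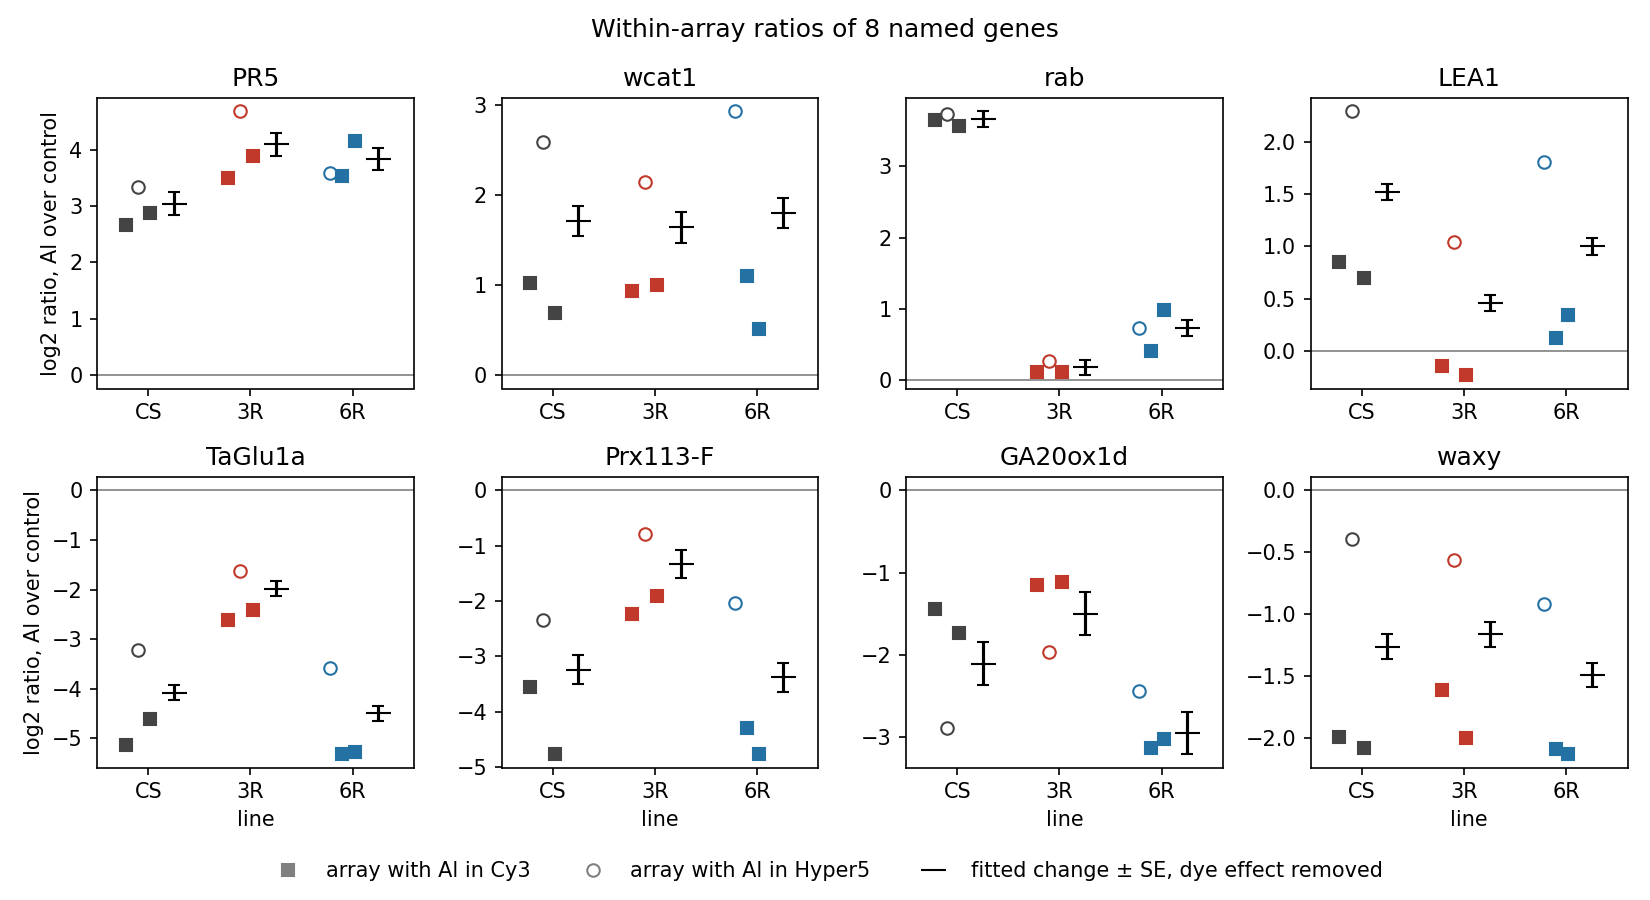
Within-array log2 ratios of Al over control for 8 named genes (vertical axis) in the 3 lines (horizontal axis). Filled squares are arrays with the Al sample in Cy3, open circles those with it in Hyper 5, and black bars give the fitted change ± SE with the dye effect removed. The ratios of rab lie at 3.56 to 3.73 in CS, 0.11 to 0.27 in 3R and 0.41 to 0.99 in 6R.

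The 3 lines shared much of the response. Between CS and 3R, 2873 probes rose in both and 2589 fell in both, where independent lists would share 403 and 369. Between CS and 6R, 4203 rose and 4079 fell in both (719 and 682 for independent lists), and between 3R and 6R 3126 rose and 2833 fell (479 and 431). PR5, wcat1, Glc1, COMT1 and PIMT were among 2751 probes that rose in all 3 lines, and TaGlu1a, Prx113-F, waxy and the GA20ox1 genes among 2461 that fell in all 3. Opposite calls were found for 40 probes between CS and 3R, 40 between CS and 6R and 15 between 3R and 6R. Pearson's r of the line effects across probes, which are not independent replicates, was 0.804 for CS and 3R, 0.887 for CS and 6R and 0.868 for 3R and 6R. The lines have separate control samples, and the shared dye term alone gives 0.04.

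Where the responses of 3R and CS differed, that of 3R was mostly the smaller one. The fall of TaGlu1a was smaller in 3R by 2.10 ± 0.21 log2 units (SE, 3 arrays per line, adjusted p = 0.0042), that of Prx113-F by 1.91 ± 0.36 and that of Taglu1b by 1.79 ± 0.27. The gene rab rose in CS and did not pass in 3R, a difference of -3.48 ± 0.15 (adjusted p = 0.00028). Its 3R samples lay near the floor, at 6.10 and 6.27, where a change is compressed, so the size of this difference is not exact. LEA1 rose less in 3R, by -1.06 ± 0.12 (adjusted p = 0.0056).

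Past the threshold were also WGA1, which rose in CS and fell in 3R (log2 -0.69, difference -1.36, adjusted p = 0.035), Glc1 (-0.87) and U2AF65a (-0.82). Of LOC numbers, LOC542888, near the floor in 3R control samples, differed by -3.81 and LOC606367 by -0.98, and LOC100136980 by 2.78 and LOC606391 by 1.78. In the upward direction 3 named genes passed. The named probes of smallest p that did not pass were tubb2 (0.55, adjusted p = 0.10), a second probe of Prx113-F (1.84, 0.10), amy1 (0.90, 0.13), tubb1 (0.52, 0.14) and PDI (0.72, 0.14). The dehydrin and LEA list was lower in 3R (camera, adjusted p = 0.0035, with 2 of 10 probes lower, rab and LEA1, and adjusted p = 0.13 with an estimated correlation).

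In all, 831 probes differed, 487 upwards and 344 downwards, and 733 of them (88.2%) had the smaller absolute change in 3R, while 244 of the 831 had opposite signs in the 2 lines. The spread of the dye effect over probes, which does not concern Al, was also smaller in 3R, at 0.777 of that in CS, and after scaling ratios to one spread 623 probes differed, 431 of them smaller in 3R. With the slide as a further block 21 probes differed, without the dye term 129 and without the array block 122. On slide 3 alone the mean difference over the 831 probes in their direction was 1.53, against 1.496 pooled, and since slide 3 helped to choose these probes this does not show that the calls hold without a slide effect. Without 3R replicate 1, 2 or 3 there were 335, 403 and 294, and without CS replicate 1 or 3 there were 472 and 395. The share upwards was 58.6%, and 34.4% without the array block and 38.1% with the slide as a further block.

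Between 6R and CS few differences of responses passed the threshold. At an unadjusted p under 0.05 in limma the numbers lay closer together. They were 4075 probes for 6R minus CS, 4822 for 3R minus CS and 4889 for 3R minus 6R. Few calls therefore do not show that few responses differ. The rise of rab was smaller in 6R by -2.93 ± 0.15 (SE, 3 arrays per line, 7.63-fold, adjusted p = 9e-04), and that of LOC542888 by -3.24 (adjusted p = 0.0056). The 6R control samples lay near the floor for rab (6.24), so its difference is not exact either. Named genes without a call of smallest p were, upwards, PsbO (0.81, adjusted p = 0.22), another probe of Prx113-F (2.82-fold, 0.32), Ss1 (1.38, 0.43), PR5 (0.79, 0.45) and VTE5 (0.42, 0.54). The probe of Prx113-F named for the single lines fell 9.48-fold in CS and 10.4-fold in 6R, so it does not share that direction. Downwards they were WGA1 (-1.34, 0.095), SH6.2 (-0.57, 0.11), amy1 (-0.88, 0.14), GA3ox2-2 (-0.87, 0.16) and Eif4B (-0.68, 0.17).

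The dehydrin and LEA list was lower in 6R than in CS (camera, adjusted p = 5.7e-05, with 1 of 10 probes lower, 2 adjusted over the list alone, and adjusted p = 0.052 with an estimated correlation). The ha1 probes and the sulfur and methionine list were also called lower (adjusted p = 0.0019 each, and adjusted p = 0.56 each with an estimated correlation), although none of their 5 and 13 probes passed. In all, 144 probes differed, 74 upwards and 70 downwards, and 105 had the smaller absolute change in 6R. On slide 3, which helped to choose them, their mean difference was 1.53 against 1.69 pooled, with the slide as a further block no probe passed in limma (1766 at an unadjusted p under 0.05), without the dye term 43 and without the array block 47, and 15 passed when the 2 lines were fitted alone. Leaving out 6R replicate 1 or 2 gave 63 and 92, CS replicate 1, 2 or 3 gave 72, 76 and 67, and 3R replicate 1 or 3, which enter through the shared spread and dye term, gave 77 and 67. The balance of directions did not hold, with 8.5% of the calls upwards without the array block, 13.3% with the 2 lines fitted alone and 23.3% without the dye term.

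Between 3R and 6R the falls of TaGlu1a (2.51 ± 0.21 log2 units, SE, 3 arrays per line, adjusted p = 0.0039), Prx113-F (2.05), Taglu1b (1.78) and amy1 (1.11) were smaller in 3R, and so was the rise of Glc1 (-0.95, adjusted p = 0.028). LOC100136980 and LOC606353 differed by 2.71 and 1.98, and LOC543097 and LOC606367 by -1.54 and -0.88. Named genes of smallest p without a call were PMM (0.97, adjusted p = 0.071), PDI (0.88, 0.10), GA20ox1a (1.12, 0.14), WPEAMT (0.72, 0.15) and GA20ox1d (1.45, 0.15) upwards, and U2AF65a (-0.79, 0.066), LEA1 (-0.54, 0.10), rab (-0.55, 0.19), tubb3 (-0.29, 0.29) and a second probe of Glc1 (-0.57, 0.36) downwards. The Al samples of 6R lay near the floor for GA20ox1a and GA20ox1d. For rab the 3R samples and the 6R control samples did, so these 3 differences are not exact. Reference genes fell less in 3R by the list test (camera, adjusted p = 0.00031, and adjusted p = 0.41 with an estimated correlation) and ha1 likewise (0.037, and adjusted p = 0.49 with an estimated correlation), with no single probe of either passing. In all 492 probes differed, 310 upwards and 182 downwards, and 467 (94.9%) had the smaller absolute change in 3R. The mean difference over them was 1.47 within slide 1 and 1.52 within slide 3, against 1.48 pooled, on probes chosen from these same arrays, and with the slide as a further block 154 passed, without the dye term 41 and without the array block 16. Leaving out 3R replicate 1, 2 or 3 gave 86, 229 and 93, 6R replicate 1 or 2 gave 200 and 216, and CS replicate 3 gave 325.

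**Figure D3:**
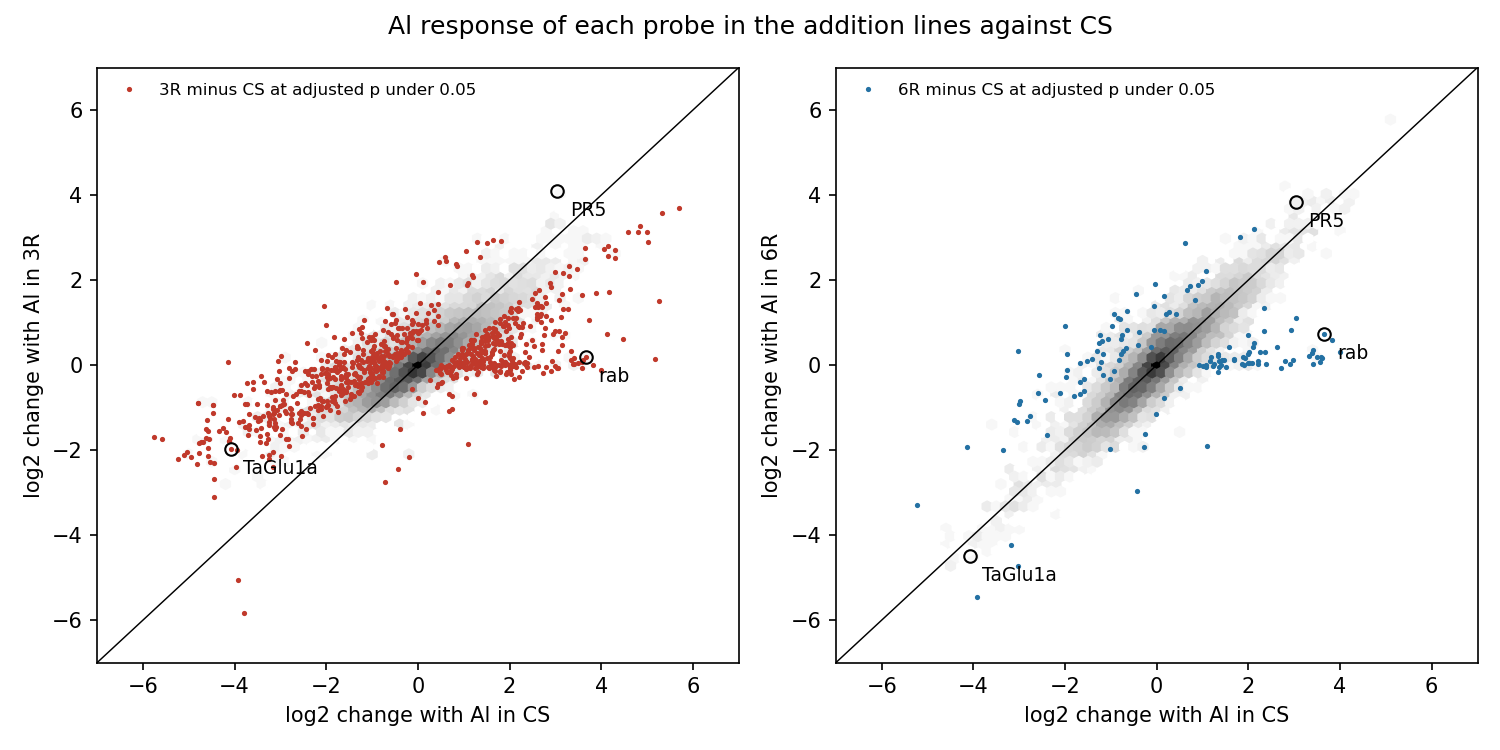
Fitted log2 change with Al of every probe in 3R (left) and 6R (right) against that in CS, with grey cells for the number of probes on a log scale, coloured points for probes whose response differs from CS at adjusted p under 0.05 and the diagonal of equal response. The 831 coloured points for 3R and the 144 for 6R include rab, at 3.66 in CS against 0.18 and 0.73.

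Without Al, 3R had lower levels than CS of hsp16.9A (-1.32 ± 0.22 log2 units, SE, n = 3 samples per line, adjusted p = 0.005) and of rab (-0.88 ± 0.16, adjusted p = 0.0076), and a higher level of TaDMAS1, an enzyme of iron-chelating mugineic acid synthesis (1.91 ± 0.40, adjusted p = 0.021). LOC543421 was higher by 1.52 and LOC100037574 by 1.81, and LOC542898 and LOC543362 were lower, at -2.45 and -2.42. For rab and LOC543362 the 3R control samples lay near the floor, so the sizes of these differences are not exact. Named genes of smallest p without a call were SH6.2 (0.64, adjusted p = 0.052), the invertase gene IVR1 (1.51, 0.12) tubb1 (0.52, 0.13), a second probe of TaDMAS1 (1.09, 0.16) and GA20ox1a (1.03, 0.17) upwards, and WPEAMT (-1.17, 0.068), PsbP (-0.79, 0.077), W55c (-0.45, 0.087), ALPb-7D (-0.59, 0.094) and HGGT (-0.29, 0.17) downwards. The photosynthesis list and the sulfur list were higher in 3R (camera, adjusted p = 0.00019 each, and adjusted p = 0.20 and adjusted p = 0.19 with an estimated correlation), with no probe of either passing, and the metal list too (0.033, and adjusted p = 0.19 with an estimated correlation), with 1 of 7 probes higher, from TaDMAS1, or 2 adjusted over the list alone.

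In all, 1297 probes differed, 94 higher and 1203 lower in 3R. The lines were normalized separately, and this split depends on it: after quantile normalization across all samples 203 were higher and 495 lower, and after median centring, which moves the median of all probes by 0.24, 1745 were higher and 767 lower. With the slide as a block 283 differed, on slide 3 alone, whose samples helped to choose the probes, the mean difference in the pooled direction was 1.53 against 1.59, and without 3R replicate 1, 2 or 3 or CS replicate 2 there were 769, 797, 844 and 779.

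Between 6R and CS no named gene passed in the control samples. The smallest p among them belonged to TaDMAS1 (1.92 higher in 6R, adjusted p = 0.095), amy1 (0.96, 0.14), GA20ox1a (1.49, 0.20), IVR1 (1.55, 0.25) and Eif4B (1.14, 0.46) upwards and to rab (-0.74, 0.13), avnla (-1.48, 0.21), HGGT (-0.36, 0.31), PsbO (-1.19, 0.45) and VTE5 (-0.63, 0.46) downwards. For rab the 6R control samples lay near the floor, so the size of its difference is not exact. The photosynthesis and sulfur lists were called higher (camera, adjusted p = 5e-04 each, and adjusted p = 0.17 each with an estimated correlation), as were ha1 (0.011, and adjusted p = 0.17 with an estimated correlation) and the pathogenesis-related list (0.034, and adjusted p = 0.17 with an estimated correlation), with no single probe of these lists passing. Over all probes 28 differed, 8 higher and 20 lower in 6R, and with a common quantile normalization 13 and 11. With the slide as a block 3 differed, on slide 3 alone, whose samples helped to choose the probes, the mean difference was 1.63 against 1.66 pooled, and without 3R replicate 1, 6R replicate 1, CS replicate 1 or CS replicate 2 there were 16, 17, 10 and 14.

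Between 3R and 6R, hsp16.9A was lower in 3R without Al (-1.13 ± 0.22 log2 units, SE, n = 3 samples per line, adjusted p = 0.021). LOC543421 and LOC100136989 were higher by 1.55 and 1.20, and LOC543362 (near the floor in 3R) and LOC542898 were lower, at -2.37 and -1.77. Named genes of smallest p without a call were SH6.2 (0.54, adjusted p = 0.21), VTE5 (0.63, 0.37), wali1 (1.08, 0.38), avnla (1.03, 0.56) and Tubb4 (0.45, 0.58) upwards and amy1 (-0.79, 0.11), wcat1 (-1.10, 0.21), lgul (-0.58, 0.31), thionin (-0.62, 0.34) and LEA1 (-0.55, 0.36) downwards. No list was called in this comparison. Over all probes 555 differed, 66 higher and 489 lower in 3R, and 113 and 389 with a common quantile normalization. Their mean difference in the pooled direction was 1.97 within slide 1 and 1.98 within slide 3, against 1.97 pooled, on probes chosen from these samples, and without 3R replicate 1 or 3 there were 340 and 335.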

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

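The tests of shrunken ratios, of the level scale and of the slide for the smaller responses in 3R, all tests of the larger rise in CS, and the test of swapped channel labels were chosen after their results or values close to them had been seen, and the tests of the intensity curve and of other splits of the samples before. The explanation by shrunken ratios was given its wording after its value was known.

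Each result here was picked out because a limma test of the difference between the Al responses of 2 lines passed. Between 3R and CS 831 probes differed, between 6R and CS 144 and between 3R and 6R 492. For 3R minus CS the named differences were 2.10 for TaGlu1a, 1.91 for Prx113-F, 1.79 for Taglu1b, -3.48 for rab, -1.36 for WGA1, -1.06 for LEA1, -0.87 for Glc1, -0.82 for U2AF65a, 2.78 for LOC100136980, 1.78 for LOC606391, -3.81 for LOC542888 and -0.98 for LOC606367. For 6R minus CS they were -2.93 for rab and -3.24 for LOC542888. For 3R minus 6R they were 2.51 for TaGlu1a, 2.05 for Prx113-F, 1.78 for Taglu1b, 1.11 for amy1, -0.95 for Glc1, 2.71 for LOC100136980, 1.98 for LOC606353, -1.54 for LOC543097 and -0.88 for LOC606367.

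Responses to Al were smaller in 3R: over the 16392 probes called in the mean of the lines, the mean change in the called direction was 0.54 log2 units in 3R, 0.72 in CS and 0.78 in 6R. A compressed scale of the log2 levels is not excluded. Their standard deviation in 3R was 0.978 of that in CS, but the quartiles lay closer together. The lower and upper quartiles were 6.06 and 9.61 in 3R against 6.10 and 9.96 in CS. A slide effect is excluded against 6R, which shares its slides with 3R, by a difference of -0.27 within slide 1 and -0.19 on slide 3. Against CS the slide stays open, because the -0.23 on slide 3 rests on 1 array per line. With the slide as a further block the 733 probes of smaller size in 3R kept a median difference of 1.34 (median SE 0.26) against 1.35 (0.17). Of these probes 19 were called in limma on 3 residual degrees of freedom in place of 5, and 718 had an unadjusted p under 0.05. As the same arrays chose these probes, neither the kept size nor the lost calls decide. Ratios between the channels may be shrunk in the 3R arrays, because the dye effect, which has nothing to do with Al, had 0.777 of its CS spread (0.721 to 0.839 over 4 pairs of arrays), beside 0.752 for the Al response, but against 6R these were 0.874 (0.804 to 0.936) and 0.721, and after scaling to one spread, an alternative chosen after seeing the data, 359 of 404 differing probes were still smaller in 3R, which argues against shrinkage as the whole cause there. After the same scaling 431 of 623 were smaller in 3R than in CS, and a smaller response that belongs to the 3R line stays open, untested.

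A set of 60 probes, rab among them, rose in CS and by more than in both addition lines, with median changes of 2.01 in CS, -0.01 in 3R and 0.12 in 6R, and 4 of them had a call in 3R and 11 in 6R. The spread of the dye effect over all probes was 0.889 of that in CS in 6R (0.819 to 0.982 over 4 ratios of array pairs) and 0.777 in 3R. These values are far from the factor between the medians of the set. However, the 60 probes were chosen on these arrays for a smaller response in both addition lines. That choice sets the factor low beforehand, so shrunken ratios are not excluded by it. For the 12 probes whose control samples lay above 6.3 in both addition lines, the medians were 2.01 in CS, -0.17 in 3R and 0.11 in 6R. The same choice favours small responses in 3R and 6R, so these medians do not exclude a signal floor. For the other 48 probes the floor compresses any response and stays open too, and 29 of the 60 lay under 6.3 in all 4 groups of the addition lines. The slide stays open too: with the slide as a further block the median of the smaller difference was 1.67 (median SE 0.22) against 1.79 (0.17), and 0 of the 60 were called in both limma comparisons (60 at an unadjusted p under 0.05), as that fit rests on fewer degrees of freedom and, between CS and the others, on slide 3. Both comparisons share the CS arrays, whose replicate noise alone gave the differences a covariance of 0.022 and a correlation of 0.49 in simulated data, against 0.054 and 0.52 here. The simulation gave all lines one spread per probe, so noisier CS arrays could raise the covariance by themselves. Whether noise leaves part of the agreement over is therefore not decided. The slide of CS replicates 1 and 2 and a difference that belongs to the lines stay open as well.

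The dye effect was large, with a standard deviation over probes of 0.453 against 0.532 for the mean Al response, and 17928 probes were called for it. An intensity-dependent dye bias stays open: a curve on mean intensity took up 0.466% of its variance, but the 2 channels of an array had already been brought to one distribution (sorted values within 0.004 in a line), which removes most of such a curve beforehand, so that the low bound set before the test cannot exclude it. For swapped channel labels, 0 of 9 arrays correlated better with those of the opposite dye orientation, which argues against a wrong dye field on a single array. An exchange of the Al and control labels together with their dyes would leave that count at 0. It would also turn the Al part of that array's ratios around. Ratios of arrays of one dye orientation correlated at 0.805 to 0.909, which argues against such an exchange on a single array. No biological explanation was tested.

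Other splits of the samples were run for the 10 comparisons of groups, and not for shared probes, lists or the dye effect. For the mean of the lines, 1 of 100 exchanges of samples within arrays called as many probes as the 16392, namely the true one, and the highest other called 9366. For the responses in CS, 3R and 6R, for their 3 differences and for the 3 comparisons of control levels, 1 of 10 splits, the true one, called as many, which is too few splits to exclude chance at 5%. The highest other split called 0 probes for each response and difference, and 9, 1 and 1 for the levels of 3R minus CS, 6R minus CS and 3R minus 6R. In most other splits of a single line, only 1 array had its 2 samples on different sides. With the array kept as a block, the response then rested on that array, so 0 calls were close to fixed beforehand. The remaining splits left the Al response in the residual spread. The 0 calls in single lines therefore say little about chance.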

How the results depend on the processing

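The loess, the dye term for each line and the scaled ratios were chosen after seeing the data, all other alternatives before. Where a value below moved, the cause was not tested, except that stricter thresholds call fewer probes by construction. Alternatives were followed for the 146 gene results past the threshold, some of them for fewer, and none of these results changed its direction. For responses and levels this was largely fixed beforehand. Their genes had been chosen for the same sign in all arrays, or for levels without overlap, so a reversal was hardly possible. Differences of responses were not chosen in that way. Of the 146, 82 kept their call without the dye term, 87 without the array block, 143 with quantile normalization across all samples and 146 with median centring. However, 134 of them rest on ratios within arrays, and samples of a line already shared a median and nearly a distribution. Both normalizations therefore shift the channels of an array almost alike. For these 134 the kept calls were largely fixed beforehand and say little about normalization. With the slide as a further block 90 of 134 results kept their call and 44 lost it. For those on CS and on the mean this does not retest the response, because a slide held CS arrays alone. Of the 12 results on control levels 7 kept their call and 5 lost it with the slide as a fixed block. With control samples alone the numbers were likewise 7 and 5. Signal over the floor limits the dim probes. The removal of the dimmest probes took away no probe of the 146 results, and 145 of them kept their call. Their changes were fitted to the same values as before, so this says nothing about the effect of the floor on them.

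Without the array block, which drops the pairing, the counts were 2388 for Al in CS, 735 in 3R, 2716 in 6R and 6240 in the mean, and 122, 47 and 16 for the differences 3R minus CS, 6R minus CS and 3R minus 6R. With the array as a random block 6R minus CS gave 249. Without the dye term they were 3912, 1691, 4430, 9164, 129, 43 and 41 in that order, the probes shared in direction 1410 for CS and 3R, 3035 for CS and 6R and 1535 for 3R and 6R, the control level of 3R minus CS 819, and the lists called 2 in 3R and 0 for 3R minus 6R.

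With the slide as a further block, Al in CS gave 1268, the mean 8156, and the 3 differences 21, 0 and 154. Because a slide held CS arrays alone, the counts for CS and for the mean do not retest those responses. On the arrays of the lines compared alone, 3R gave 10587, 6R 7578 and 6R minus CS 15. With a trended robust prior 3R minus 6R gave 258 and the level of 6R minus CS 60. With at least 2-fold change, CS gave 3315, 3R 1756, 6R 3727 and the mean 2785. At an adjusted p under 0.01, CS gave 6178, 3R 3107, 6R 7597, the differences 276, 50 and 118, and the levels of 3R minus CS, 6R minus CS and 3R minus 6R 547, 12 and 319. With a dye term for each line 6R minus CS gave 92 and 3R minus 6R 293.

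For control levels of 3R minus CS, quantile normalization across all samples gave 698, median centring 2512, the slide as a fixed block 283, control samples alone 670 and the mean of control and Al samples 2504. For 6R minus CS the slide block gave 3, control samples alone 4 and the mean of both conditions 123, and for 3R minus 6R the last 2 gave 307 and 1053.

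List calls all fell to 0 with an estimated correlation, for each of the 9 comparisons that had any. With fry, CS had 4, 3R 3, 6R 5, the mean 7, 6R minus CS 1, 3R minus 6R 0, and the levels of 3R minus CS 1 and of 6R minus CS 0. The lists called were not always the same. For the levels of 3R minus CS, photosynthesis, sulfur and metal chelation lost their call, and dehydrins and LEA proteins were called lower (fry, adjusted p = 0.041). For Al in 6R the ha1 list lost its call (fry, adjusted p = 0.055), while the dehydrin, histone and pathogenesis-related lists gained one.

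Leaving out each array in turn gave 6803 to 11254 for CS, 1905 to 8183 for 3R, 6419 to 13151 for 6R and 13154 to 16818 for the mean. It gave 294 to 1016 for 3R minus CS, 63 to 167 for 6R minus CS and 86 to 611 for 3R minus 6R, and for the levels 769 to 1297, 10 to 30 and 335 to 574 in the same order.

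The balance of directions moved as well. Of the probes called for 6R minus CS, 51.4% were upwards, against 8.5% without the array block, 13.3% on the lines alone, 23.3% without the dye term, 32% at an adjusted p under 0.01, 37% with a dye term for each line, 41.3% with the loess and 31.3% to 40.3% without 3R replicate 1 or 3, 6R replicate 1 or any CS replicate. For 3R minus CS the share fell from 58.6% to 34.4% without the array block and 38.1% with the slide as a further block, and for 3R minus 6R it went from 63% to 75% and, with the trended robust prior, 73.3%. For Al in 3R it went from 51.7% to 69.5% without the array block, 62.8% without the dye term, 71.2% at 2-fold and 62.4% without 3R replicate 2, and for the mean from 47.5% to 59.1% at 2-fold. Of the 28 probes for the level of 6R minus CS, 28.6% were higher, against 40% with median centring or the trended robust prior, 54.2% with common quantiles, 0% with the slide block or control samples alone, and 43.3%, 10% and 5.3% without 6R replicate 2, CS replicate 1 and CS replicate 3. For the levels of 3R minus CS the share higher was 7.2%, 29.1% with common quantiles and 69.5% with median centring, and for 3R minus 6R 11.9%, 22.5% and 24.5%.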

Other observations

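Lists with few probes are given here as values. Of the 3 probes of the metallothionein-like gene wali1 none passed in limma in CS, where they stood at 0.80, 0.71 and 0.55 (adjusted p = 0.07, 0.14 and 0.36), and the first alone passed in 3R and in 6R, with 2 not passing in each. The glutathione S-transferase gene GSTZ1 stood at 0.08 in CS, 0.06 in 3R and 0.03 in 6R, and the ribosomal protein genes RPL9 and RPS29 at -0.02 and 0.05 in the mean of the lines, none of them past the threshold. All 3 probes of the peroxidase gene Prx113-F fell in CS, and 1 of them in 3R and in 6R. Of the 5 probes of pathogenesis-related proteins PR5 alone rose, in each line, and in 6R the list had a median of -0.02 and a mean of 0.68. In the sulfur and methionine list, 2 of 13 probes, of SAMS, rose in CS, and in 6R 1 of SAMS rose and 3 of the adenosylhomocysteinase gene SH6.2 fell. The 2 probes of 1-FEH went opposite ways in the mean of the lines (-0.56 and 0.21).

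Counted by gene, 52 of 123 symbols with a gene name (121 distinct names) had a call for Al in CS (19 up, 33 down), 36 in 3R (15 up, 21 down) and 54 in 6R (17 up, 37 down). Another 45 probes fell in CS and differed from both addition lines, with median changes of -1.67 in CS, -0.07 in 3R and -0.14 in 6R, and of these 17 also had a call in 3R and 30 in 6R.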
